A study of Drosophila melanogaster with 2 samples.

How the data were processed

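Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old, that carried gfzf fused at its C-terminus to green fluorescent protein (GFP). An antibody against GFP was used, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The labels name 2 biological replicates, which form a single group, so no contrast between conditions was possible. They do not say whether the replicates came from separate embryo collections.

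Peak lists were deposited for each replicate, for the reads of both replicates pooled, and for the set that passed the authors' irreproducible discovery rate (IDR) filter, called the optimal set here. Each list was deposited on the dm6 and dm3 builds. The lists for single replicates and for the pool held 30000 lines each and were the relaxed input of the IDR filter. Column 7 of each list is the peak signal that the authors' peak caller gave, on a scale that is not stated and that was therefore compared only within a list. Column 9 is the deposited −log10 of the q-value. It took a single value throughout the optimal set on dm6, so it could not rank peaks there. Column 10 gives the summit position. The aligner, the peak caller, the IDR settings and the sequencing depth are not given in the sources used here, and per the deposited file inventory both replicates shared 1 control entry. Control reads, alignments and signal tracks were not analysed here. Because depth is unknown, no interval in the text covers read counting error. Binomial intervals over peaks or genes (exact Clopper-Pearson, 95%) treat these as independent.

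Analyses used the optimal set on dm6, the dm6 reference sequence and the Ensembl release 115 annotation of the same assembly. No peak of the pooled list ended past its reference chromosome. Computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A summit was assigned to a promoter when it lay within 250 bp of the transcription start site (TSS) of a protein-coding transcript, and a gene was bound when a summit lay that close to any of its TSSs. The background was 13968 protein-coding genes on chromosomes that carried at least 1 peak of the relaxed pooled list.

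Replicate peaks were linked to optimal peaks by summits within 100 bp. The promoter share was tested one-sided against 10000 circular shifts of all summits within each chromosome. Overlap of the replicates was set beside 100 such shifts. The 25 gene lists were tested with two-sided Fisher exact tests and Benjamini-Hochberg adjustment. The 17 motifs and 8192 merged 7-mers were tested with two-sided exact McNemar tests of a window of 50 bp on each side of the summit against an equal window 500 bp to 1 random side, with adjustment within each family. For core promoters, 1 TSS per gene was taken without reference to the peaks. Motifs from −100 to 50 bp were compared between bound and unbound promoters by two-sided Fisher exact tests. In all motif tests a match counted on either strand and at any position of the window. A value of 0.5 was added to each cell of a table that held a 0 when its odds ratio was computed. In log2 ratios of discordant pairs, 0.5 was always added to both counts. Median log2 signal with and without a motif was compared by a two-sided permutation test with 100000 resamples, and its standard error (SE) came from 1000 bootstrap draws. A p-value printed as 0 was too small for double precision.

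The samples, tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes at the 10 strongest promoter peaks that both replicates' lists held, up to 2 bound members with the highest signal per list, up to 2 unbound members in alphabetical order for lists that passed, 10 chromatin regulators whatever their values, and the 5 strongest peaks outside promoters. Alternatives changed the TSS distance, window, flank, overlap rule, background, TSS choice and peak set. Each replicate was left out by taking the 5007 strongest peaks of the other. Settings that kept only the strongest summit of an interval, used the other flank, counted non-coding TSSs or used the core of Motif 1 in the signal test were added after the data were seen.

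The tests of gene lists, summit motifs, 7-mers and the promoter share were tested on simulated data; the other tests were not. Among 13968 genes, 3 of 10 lists of 20 genes bound at 4 times the odds were called, and 0 of 100 unchanged lists were. Their median estimated log2 odds ratio was 1.93 where 2 was simulated. With the real list sizes, 12 of 13 changed lists and 0 of 12 unchanged lists were called. In the list simulations each gene was bound independently of its neighbours, whereas in the data 1 summit can bind 2 genes. The rates of false calls for lists therefore need not carry over to the data. A planted motif was called in 20 of 20 draws, while 1 of 300 tests of unrelated motifs was called. Unrelated 7-mers numbered 0.45 per draw on average among 8192. The windows of these draws lay at random positions of the genome. They lacked the difference in sequence between promoter summits and flanks, so these rates of false calls do not carry over to the data. Uniformly placed summits gave a permutation p of 0.856 in the promoter test.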

Results

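The series mapped where a GFP fusion of gfzf binds in whole embryos. The gene gfzf encodes a nuclear protein with FLYWCH zinc fingers and a glutathione S-transferase domain, and it is known as a hybrid incompatibility gene. The data comprise 2 biological replicates in 1 group, so the design implies a catalogue of binding sites and their features. The signal values are the authors' peak scores, and the sequencing depth is unknown.

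The optimal set held 5007 peaks on dm6, which occupied 4362 distinct intervals because 645 lines repeated another line's interval with a different summit. Their median signal was 361 and ranged from 88.4 to 15685. These peaks were the 5007 strongest of the relaxed pooled list. The deposited set on dm3 held 4971 peaks.

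The strongest peaks of the replicates lay largely at the same places. The strongest peak, in the shared promoter region of CG7655 and alt, ranked 1 in both replicates' lists, and the peak at Galphai, a G protein alpha subunit gene, ranked 3 and 2. The peak at gfzf itself ranked 306 in replicate 1 and 192 in replicate 2. Of the optimal peaks, 4865 (97.2%) had a summit within 100 bp in both replicates' lists. Spearman's rho of their signal was 0.960 across peaks, which are not independent replicates. The optimal set came from an IDR filter on these replicates and equals the 5007 strongest lines of their pooled list. Both values are therefore conditioned on that choice of peaks. Among the 5007 strongest peaks of replicate 1, 4648 (92.8%, 95% interval 92.1 to 93.5) overlapped a peak among the 5007 strongest of replicate 2, against a mean of 3.53% and a highest value of 4.75% over 100 circular shifts.

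**Figure D1:**
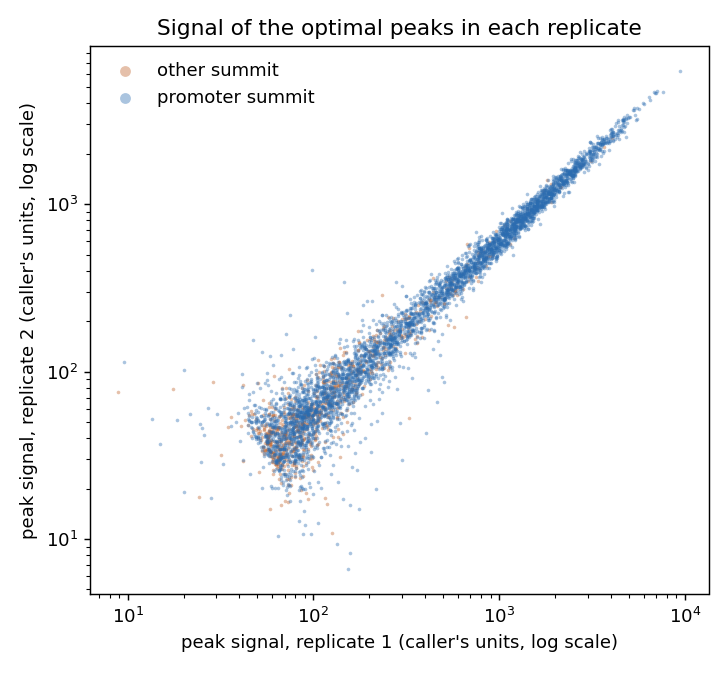
Signal of each optimal peak in replicate 1 (x axis) and replicate 2 (y axis), both in the peak caller's units on log scales, for the 4865 peaks linked in both; blue points are promoter summits and orange points other summits. The points follow a single band (Spearman's rho 0.960) that widens at low signal.

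Most gfzf summits lay at promoters of protein-coding genes. Of the 5007 summits, 4188 (83.6%, 95% interval 82.6 to 84.7) lay within 250 bp of a protein-coding TSS, against a mean of 6.28% over shifted positions. Introns held 5.89% of summits and 40.8% of the genome, coding exons 0.579% and 15.7%, and intergenic sequence 8.31% and 31.1%. Promoter summits lay a median of 37 bp upstream of the nearest TSS (offset −37 bp, quartiles −70 and −10). The share exceeded every shift (highest 14.5%), giving a permutation p of 0.0001, the smallest that 10000 shifts allow in a one-sided test.

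The 10 strongest promoter peaks marked 15 genes. The strongest lay on chromosome 3R from 17681993 to 17683231 (signal 15685), with its summit at 17682600 between CG7655 and alt, 69 and 85 bp from their TSSs. The next lay on X from 2079918 to 2081002 (signal 12332), between CG16903 and Unc-76, the latter encoding an axonal transport adaptor. Galphai on 3L had a signal of 11789, and RpL30 on 2L, a large ribosomal subunit gene, had 11553. The pairs CG14710 and Jupiter, CG13484 and Frl, and Atg8a and BTBD9 each shared 1 peak, with signals of 11497, 11475 and 10760. Jupiter encodes a microtubule-associated protein, Frl a formin and Atg8a a ubiquitin-like autophagy protein. Lk6, a protein kinase gene, had 10654, ATPsynC, a subunit of ATP synthase, 9963, and Socs36E, a JAK-STAT inhibitor, 9923. All 10 summits lay outside annotated protein-coding gene bodies, and each ranked among the first 10 peaks in both replicates.

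The 5 strongest peaks outside promoters still lay near a gene start. A peak on 2L at 490303 (signal 6518) lay in a 5′ untranslated region (UTR) of ush, 532 bp from its TSS, and a peak on 3L at 292348 (5830) lay in an intron of RhoGEF3, 344 bp from its TSS. A peak on 2R at 16585868 (4938) lay 261 bp from the TSS of RpLP2. A peak on 2R at 9095188 (4489) lay 85 bp from the 5′ end of Uhg4, a small nucleolar RNA host gene. The last, on 2L at 3303670 (3396), was intergenic, 430 bp from CG3277.

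In all, 4609 of 13968 protein-coding genes (33.0%, 95% interval 32.2 to 33.8) were bound. Among the 10 regulators chosen in advance, gfzf had a peak on 3R from 7150057 to 7151576 (signal 4282), with its summit in its own 5′ UTR, 224 bp from its TSS. The transgene and the endogenous gene share sequence, so the peak list does not separate them. The gene pzg had a signal of 1100.0, Chro 365, Dref, which encodes the DRE-binding factor, 304, Cp190 259, BEAF-32 250.1 and Lhr 140.3. M1BP, which encodes the Motif 1 binding protein, had no peak at its promoter, nor did Hmr or Trl, the GAGA factor gene.

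Of 25 gene lists, 14 were bound more often than other genes, 7 were bound less often and 4 did not pass the test. Cytosolic ribosomal protein genes were bound most often (75 of 93, 80.6%, log2 odds ratio 3.10 ± 0.38 SE, adjusted exact p = 4.27e-20), with RpL30 and RpL3 (signal 9368) strongest and RpL10 and RpL10Aa without a peak. Mitochondrial ribosomal protein genes were bound in 50 of 75 cases (2.03 ± 0.35, adjusted exact p = 1.28e-08), led by mRpL13 (7377) and mRpS16 (5453), whereas bonsai and mRpL14 had no peak. Genes of the respiratory chain were bound in 55 of 91 cases (1.65 ± 0.31, adjusted exact p = 3.27e-07). ATPsynC and ATPsynF (8343) led them, and ATPsynbetaL and ATPsynCF6 had no peak. Translation factor genes were bound in 37 of 54 cases (2.15 ± 0.42, adjusted exact p = 3.27e-07), including eIF2Bepsilon (7801) and eIF3k (3949) but not eEF1delta or eIF1. Proteasome genes were bound in 30 of 48 cases (1.77 ± 0.43, adjusted exact p = 6.49e-05). Prosbeta1 (6101) and Rpn2 (5074) had the strongest peaks there, and Prosalpha1 and Prosalpha1R had none.

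Genes for transcription, splicing, replication and chromatin were enriched as well against all protein-coding genes. None of the lists in this paragraph passed against genes with a relaxed pooled summit at the promoter (adjusted exact p from 0.0577 to 0.460). The Mediator list had 22 of 29 bound (log2 odds ratio 2.68, adjusted exact p = 6.26e-06), with MED4 (signal 4970) and MED10 (4757) strongest and Cdk8 and CycC unbound. RNA polymerase II and general factors had 25 of 38 (1.97, adjusted exact p = 6.60e-05), with TfIIEalpha (7787) and TfIIS (7116) bound and Polr2B and Polr2J not. The spliceosome list had 24 of 35 (2.15, adjusted exact p = 3.52e-05), with SmF (2983) and snRNP-U1-70K (2943) bound and Prp16 and Prp19 not. DNA replication had 27 of 35 (2.78, adjusted exact p = 3.27e-07), with Orc5 (3749) and RfC38 (2973) bound and dup and Mcm2 not. Cell cycle and checkpoint genes had 23 of 31 (2.55, adjusted exact p = 6.51e-06), with Wee1 (5775) and CycB3 (3497) bound and Bub1 and Cdk4 not. Polycomb group genes had 15 of 19 (2.93, adjusted exact p = 8.19e-05), with esc (4935) and Caf1-55 (3860) bound and ph-d and ph-p not. Architectural and promoter-binding proteins had 13 of 18 (2.40, adjusted exact p = 0.00112), with msl-2 (5874) and Clamp (2284), both of the dosage compensation system, bound and Ibf1 and Ibf2 not. The hybrid incompatibility and heterochromatin list, which holds gfzf, had 12 of 18 (2.02, adjusted exact p = 0.00563), with Su(var)3-7 (3203) bound and BoYb and Hmr not. Ras-MAPK signalling had 12 of 20 (1.61, adjusted exact p = 0.0193), with csw (6323) and Sos (4062) bound and aop and aos not.

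The 7 depleted lists covered chemoreceptors, odorant binding and seminal fluid proteins, midgut and fat body enzymes, cuticle proteins, patterning genes, glutathione S-transferases and muscle markers. Among 180 chemoreceptor genes, including the gustatory receptors Gr10a and Gr10b, 0 were bound, with an upper 95% limit of 2.03% (adjusted exact p = 9.62e-31). Among 98 genes for odorant binding and seminal fluid proteins, including Acp24A4, 0 were bound (upper limit 3.69%, adjusted exact p = 8.80e-17), and among 57 midgut and fat body enzyme genes, including alphaTry and Amy-d, 0 were bound (6.27%, adjusted exact p = 8.78e-10). Cuticle protein genes had 1 of 122 bound, Cpr62Ba (signal 718; adjusted exact p = 4.54e-19), and Acp1 and Ccp84Aa had no peak. Acp1 encodes an adult cuticle protein and was also counted in the seminal fluid list because of its symbol. Patterning genes had 2 of 48 bound, bcd (115) and pnr (96.5) (adjusted exact p = 4.30e-06), and the Hox genes abd-A and Abd-B had no peak. Glutathione S-transferase genes had 3 of 36 bound (log2 odds ratio −2.44 ± 0.87, adjusted exact p = 0.00145). GstE13 (317) and GstT3 (176) were among them, and GstD1 and GstD10 were not. Muscle markers had 2 of 22 bound, Tm1 (5440) and Mef2 (971) (adjusted exact p = 0.0245), and Act57B and Act87E had no peak.

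Heat shock protein genes (5 of 24, adjusted exact p = 0.289), neuron markers (2 of 19, 0.0544), germline markers (7 of 20, 0.816) and aminoacyl-tRNA synthetase genes (16 of 34, 0.108) did not pass. Bound members included Hsc70-4 (signal 4542), Hsp60A (917), Syx1A (5119), unc-13 (107), Sxl (7549), zuc (958), GlnRS (3295) and LysRS (2840). When the background was restricted to 7204 genes with a relaxed pooled summit at the promoter, 3 of the 14 enriched lists passed with an enriched share, namely cytosolic ribosomal proteins, proteasome subunits and the respiratory chain, and cuticle proteins lost their call (adjusted exact p = 0.0998), although all 14 kept a log2 odds ratio above 0 (0.50 to 2.76). Calls were also lost by the hybrid incompatibility list at a TSS distance of 100 bp (adjusted exact p = 0.128) and with 1 gene per cluster of TSSs (0.0587), Ras-MAPK signalling at 1000 bp (0.0811), architectural proteins and the Polycomb group among the strongest 2504 peaks (0.0886 and 0.0504) and muscle markers at 100 bp (0.109), among the strongest 2504 peaks (0.312), with 1 gene per cluster (0.0662) and without replicate 1 (0.0783), and neuron markers gained a call without replicate 1 (0.0145).

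**Figure D2:**
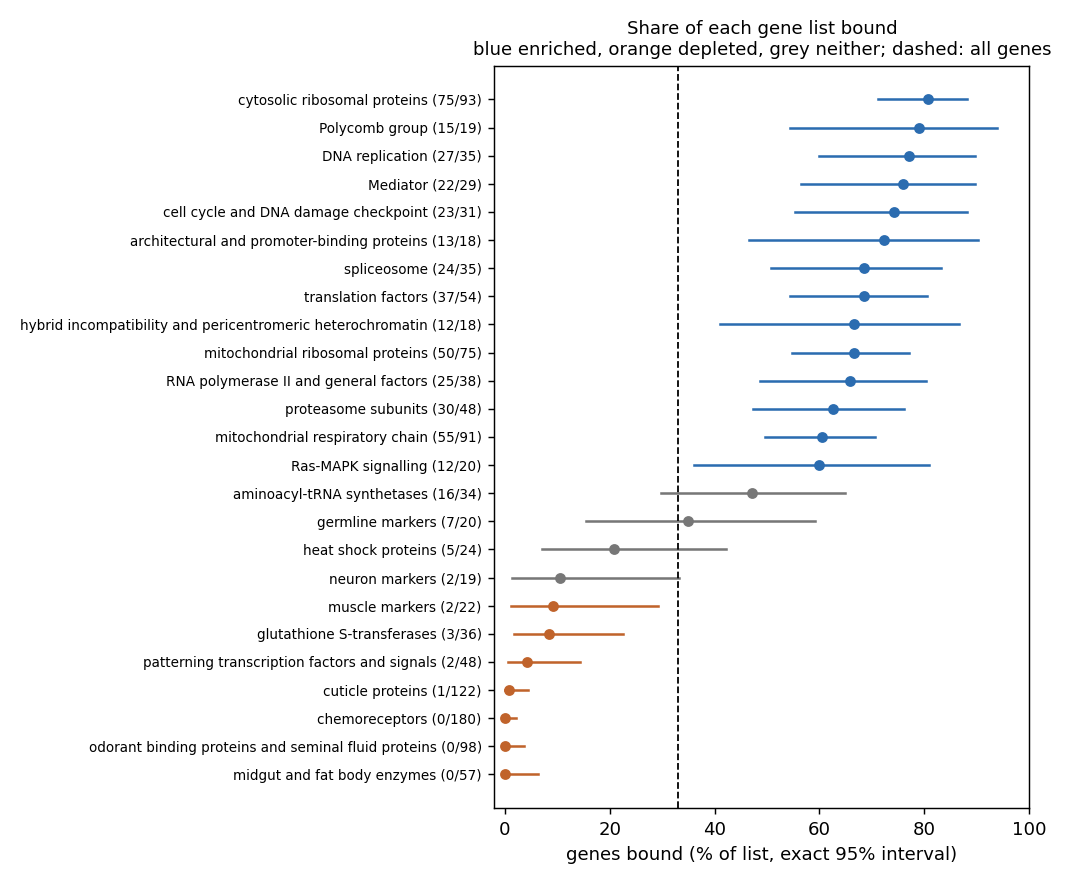
Share of the genes of each of the 25 lists with a bound promoter (x axis, percent), with exact 95% binomial intervals as lines and bound over listed genes in parentheses; the dashed line is the share of all genes (33.0%). Blue lists were enriched, orange lists depleted and grey lists neither, and shares run from 0% to 80.6%.

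Motif 1 and the DNA replication-related element (DRE) were far more frequent at summits than in flanks, although many peaks held neither. The Motif 1 core, DRE, Motif 6 or Motif 7 lay within 50 bp of 1643 summits and within 100 bp of 2311 (46.2%). The Motif 1 core GGTCACAC occurred in 642 summit windows (12.8%, 95% interval 11.9 to 13.8) and in 13 flanks (0.260%), a log2 ratio of discordant pairs of 5.57 (adjusted exact p = 1.35e-169). The full Motif 1 consensus YGGTCACACTR occurred at 6.95% of summits and 0.0399% of flanks. The DRE consensus WATCGATW occurred at 14.1% of summits and 1.24% of flanks (log2 ratio 3.75, adjusted exact p = 3.35e-144), Motif 7 at 7.01% and 0.919%, Motif 6 at 3.46% and 0.0599%, and the E-box of Ohler Motif 5 at 2.00% and 0.220%. The Pho and CTCF consensus sequences were slightly more frequent at summits (adjusted exact p = 0.0173 and 0.00872). GAGA, Zelda, DPE and TCT sequences were rarer there than in flanks, and GAGA fell from 1.68% of flanks to 0.879% of summits (adjusted exact p = 0.000624). Shuffling the letters of the Motif 1 core gave 20 sequences with log2 ratios from −4.75 to 1.18. The letters of Pho, CTCF, GAGA, Zelda, DPE and TCT were not shuffled, so base composition stays open for them. The TATA box, Initiator, MTE, Su(Hw) and heat shock elements did not pass. Pho lost its call without replicate 1 (adjusted exact p = 0.0777), with 25 bp on each side of the summit (0.118) and among the strongest 2504 peaks (0.185), where CTCF turned to a log2 ratio of −0.13. With 25 bp on each side Zelda lost its call (adjusted exact p = 0.162), and with 100 bp TCT and CTCF lost theirs (0.109 and 0.540) and the TATA box gained one (0.0232).

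The motifs could be placed at named genes. At RpL30 the core GGTCACAC lay on 2L from 19009272 to 19009279 on the minus strand, within TCCCCCCGTCGGTCACACCAACACAAAC. At Atg8a and BTBD9 it lay on X from 10768341 to 10768348 on the minus strand, within CGCGCTCACTGGTCACACACGGTCAGTC. At msl-2 there were 2 copies on the minus strand, on 2L from 3466080 to 3466087 and from 3466130 to 3466137. Each sequence is written as read on its own strand. Cp190 and Prosbeta1 carried the DRE TATCGATA, on 3R from 15275238 to 15275245 and on 2R from 16014901 to 16014908. RpL3 carried Motif 6 as TTTGGTATATTT on the minus strand of 3R from 11221813 to 11221824. Of the 10 strongest promoter peaks, those at CG7655 and alt, CG16903 and Unc-76, Galphai, Lk6, ATPsynC and Socs36E, and also the peak at gfzf, held none of Motif 1 core, DRE, Motif 6 or Motif 7 within 100 bp of the summit.

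**Figure D3:**
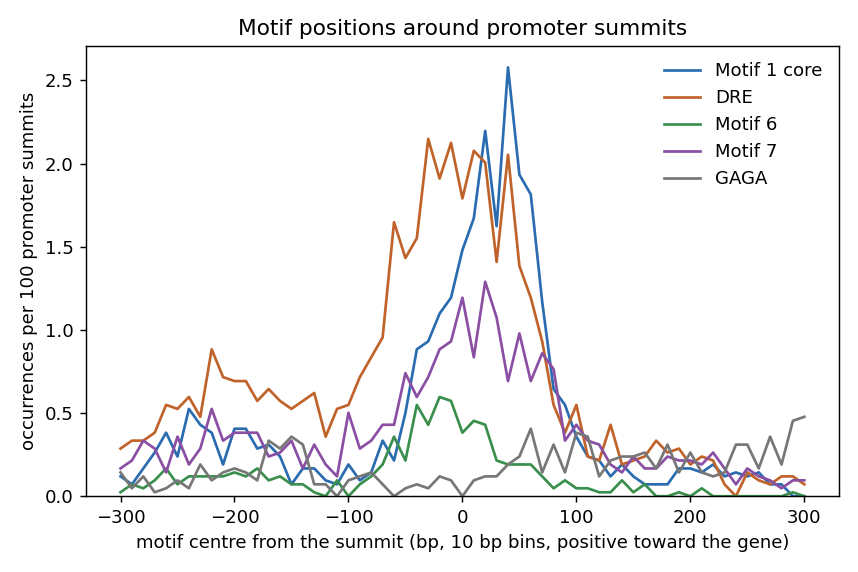
Occurrences of 5 motifs per 100 promoter summits (y axis) by distance of the motif centre from the summit in bp (x axis, 10 bp bins, positive toward the gene), for 4188 promoter summits. The Motif 1 core is most frequent in the bin at 40 bp (2.58 per 100 summits) and the DRE in the bin at −30 bp (2.15), while GAGA shows no maximum at the summit.

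A search without a motif list returned the same elements. The enriched 7-mers with the lowest exact p were ATCGATA (17.0% of summits, 1.52% of flanks), GGTCACA (14.5% and 0.959%), GTCACAC (13.6% and 0.639%), AGTGTGA (11.8% and 0.939%), CTATCGA (11.6% and 0.919%) and AAATACC (11.5% and 1.34%). Of the 20 enriched ones with the lowest exact p, 17 matched Motif 1, DRE or Motif 6 over at least 6 bases. The 7-mers CTCCTCC (0.399% and 3.59%) and CGAGGAG (0.260% and 2.94%) had the lowest exact p among depleted ones. In all 870 of 8192 7-mers were enriched and 1369 depleted at an adjusted p under 0.05. The number enriched changed with the window, from 419 with 25 bp to 1465 with 100 bp on each side of the summit. The part of these counts that base composition accounts for was not tested.

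Core promoters with Motif 1 were bound almost without exception, and those with a TATA box rarely. Of 932 core promoters with the Motif 1 core, 95.2% were bound. The core was present in 20.6% of 4315 bound and 0.466% of 9653 unbound promoters (log2 odds ratio 5.79 ± 0.22 SE, adjusted exact p = 0). Promoters with Motif 6 were bound in 90.7% of 226 cases (4.52 ± 0.33), those with the DRE in 59.1% of 1788 (1.99 ± 0.08) and those with Motif 7 in 60.9% of 1011 (1.96 ± 0.10). TATA box promoters were bound in 10.5% of 980 cases (−2.03 ± 0.15, adjusted exact p = 9.54e-55), Initiator promoters in 15.2% of 3626 (−1.68 ± 0.07) and GAGA promoters in 12.1% of 480 (−1.75 ± 0.20). Promoters with a TCT match did not pass (−0.08 ± 0.08, adjusted exact p = 0.367), but did in a promoter window from −250 to 100 bp (−0.16, adjusted exact p = 0.00868). Matches on either strand and at any place in the window counted. The Initiator, TCT and other groups are thus promoters that hold the sequence, not those with the element placed at the TSS. Among promoters of the relaxed pooled list the log2 odds ratio was 5.84 for the Motif 1 core but 0.85 ± 0.09 for the DRE, 0.85 ± 0.11 for Motif 7 and −0.65 ± 0.20 for the TATA box, and with the strongest 2504 peaks it was 0.80 ± 0.08 for the DRE and 0.78 ± 0.11 for Motif 7.

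Promoter peaks with Motif 1 were stronger than those without it. The 322 promoter peaks with the full Motif 1 within 50 bp of the summit had a median signal of 1401, against 421 for the 3866 others, 3.33-fold higher and a log2 difference of 1.73 ± 0.09 (bootstrap SE). The permutation p was 1e-05, the smallest that 100000 resamples allow. With replicate 2's signal the difference was 1.71 ± 0.10, and with replicate 1's it was 1.68 ± 0.10.

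**Figure D4:**
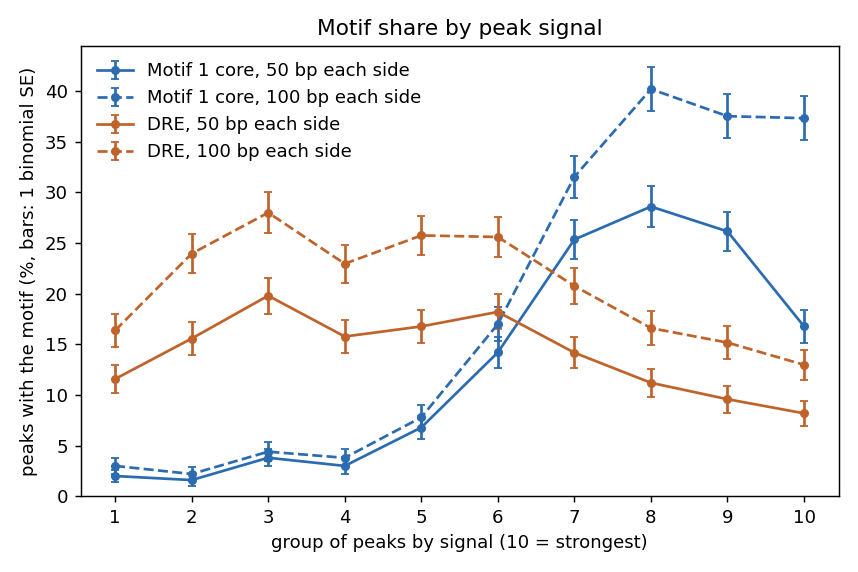
Share of peaks with the Motif 1 core (blue) or DRE (orange) in percent (y axis) for 10 groups of 500 or 501 peaks ordered by signal (x axis, 10 strongest), with 1 binomial SE as bars, within 50 bp (solid) or 100 bp (dashed) of the summit; the grouping was chosen after the data were seen. The Motif 1 core was found within 50 bp in 2.00% of the weakest group, 28.6% of group 8 and 16.8% of the strongest group.

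Genes that share a promoter region with a divergent neighbour were bound more often. Of 3598 genes with an opposite-strand TSS within 500 bp upstream, 2277 (63.3%) were bound, against 2332 of 10370 others (22.5%; log2 odds ratio 2.57 ± 0.06, two-sided Fisher exact p = 0). The pairs CG7655 and alt, CG13484 and Frl, and Atg8a and BTBD9 are examples. A summit can count for both genes of a pair, so the genes are not independent as the test and its SE assume. With a distance of 100 bp the shares were 47.7% and 19.3%. That distance does not remove the double count, since 1 summit lay 69 bp from CG7655 and 85 bp from alt. The test was not run with 1 gene per cluster of TSSs.

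Genes on the X chromosome were bound slightly more often than autosomal genes. On X 781 of 2196 genes (35.6%) were bound, among them Sxl, csw and Atg8a, against 3792 of 11669 (32.5%) on the large autosomal arms (log2 odds ratio 0.20 ± 0.07, two-sided Fisher exact p = 0.00519). Arm 2L had 29.9% bound, 2R 34.2%, 3L 32.4% and 3R 33.2%. The difference no longer passed with a TSS distance of 100 bp (exact p = 0.188) or with the strongest 2504 peaks (p = 0.284).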

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

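Some peaks of the deposited dm3 set lay on scaffolds outside the chromosome arms. The deposited optimal set on dm3 held 17 of its 4971 peaks on scaffolds outside the chromosome arms, against the 3 that a count of 0 allows. The relaxed pooled list on dm3 held 85 of 30000 lines outside the arms, and no background level for these scaffolds was at hand, so the 17 peaks are not shown to exceed the usual level. The 17 peaks included 6 on 3LHet and 4 on XHet, and their signal reached 955. The optimal set on dm6 held 0 lines outside the arms. Whether the dm3 scaffolds correspond to sequence within the dm6 arms was not examined. The 17 peaks are thus not shown to lie in sequence that the comparisons left out. The count was chosen after the data were seen, and no explanation was tested.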

How the results depend on the processing

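No paired analysis was possible because the 2 replicates form a single group. The settings that kept the strongest summit of an interval, used the other flank, counted non-coding TSSs or used the Motif 1 core were chosen after the data were seen. Of the alternative values, 457 were labelled unchanged, 35 lost and 4 gained a call in the same direction, 8 moved and 20 turned direction. A test was labelled unchanged when its call held and its sign did not turn, also where a log2 ratio fell to 0. That was so for MTE with 25 bp on each side. Counts were labelled unchanged within a fixed fold limit, which covered 4609 bound genes as reported and 3717 at 100 bp. The promoter share (67.1% to 94.0%), the Motif 1 signal difference (log2 1.27 to 2.14) and the divergent promoter difference (log2 odds ratio 1.93 to 2.97) kept their calls under each setting run for them. Taking the stronger part of the peaks left 2504 peaks and 2823 genes bound, by construction. Replicate overlap was 96.3% for the 1000 strongest peaks, 83.4% with a reciprocal overlap of 0.5 and 87.0% for summits within 100 bp. Among promoters of the relaxed pooled list 3 lists stayed enriched, and 419 or 1465 7-mers were enriched with 25 or 100 bp on each side of the summit. The X chromosome log2 odds ratio was 0.10 at a TSS distance of 100 bp and 0.090 among the strongest 2504 peaks, and did not pass. The germline list (0.13 as reported, not passed) turned to −0.12 at 100 bp, −0.019 among the strongest peaks, −0.48 with the strongest summit per interval and −0.61 in the relaxed background, and ranged from −0.18 to 0.18 with a replicate left out. Aminoacyl-tRNA synthetases (0.85, not passed) turned to −0.74 in the relaxed background. Among motifs that did not pass, Su(Hw) (−0.16) turned to 0.29 and 0.66 with 25 and 100 bp on each side and to 0.39 with the flank at 1000 bp, Initiator (−0.04) to 0.035 with 100 bp on each side, 0.019 with the flank at 1000 bp and 0.18 with the other flank, MTE (1.58) to −0.89 and −0.74 with 100 bp on each side and the far flank, and the heat shock element (0.21) to −0.18 with the far flank. With a replicate left out, Su(Hw) ranged from −0.16 to 0.63, Initiator from −0.049 to 0.057 and MTE from −0.74 to 0. CTCF (0.37) turned to −0.13 among the strongest peaks, and its core promoter odds ratio (0.35) to −0.090 from −250 to 100 bp. As reported, MTE occurred in 1 summit window and 0 flanks, Su(Hw) in 8 and 9, and the heat shock element in 7 and 6. With counts this small, a few windows can turn the sign of a ratio. No cause was tested in any of the cases above. Sequencing depth is unknown, so its effect on these values could not be measured.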

Other observations

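The gene families, paralog split, groups by signal and their test, signal by motifs other than Motif 1, the joint test of the enriched lists and its shifts, signal of the lists other than ribosomal proteins, non-coding genes and chromosome 4 were chosen after the data were seen. Nuclear pore genes were bound in 18 of 21 cases (log2 odds ratio 3.61 ± 0.90, adjusted exact p = 1.83e-06), autophagy genes in 12 of 20 (adjusted exact p = 0.0231) and Rab GTPase genes in 19 of 36 (0.0233). Cytochrome P450 genes were bound in 4 of 85 cases (−3.33 ± 0.74, adjusted exact p = 9.72e-10) and replication-dependent histone genes in 4 of 115 (−3.79 ± 0.73, adjusted exact p = 4.75e-14). Each histone gene copy counted as an independent gene in that test, which was not run with 1 gene per cluster of TSSs. Whether reads could be placed at single histone copies was not examined, so these values do not show depletion of binding there. V-ATPase genes did not pass (16 of 33, adjusted exact p = 0.0648).

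Genes marked as copies by the suffix of their symbols were mostly unbound, 5 of 40 being bound against 155 of 192 other genes of the same lists. Among proteasome genes, 1 of 16 copies with an R or T suffix, Prosbeta2R2, was bound, against 29 of 32 other subunits (two-sided Fisher exact p = 1.09e-08). In the respiratory chain list, 1 of 19 copies with an L suffix, COX7AL, was bound, against 54 of 72 others (exact p = 2.80e-08). ND-MNLL, whose name ends in L without marking a copy, was counted among the others, a choice made after its value was seen. Genes of the cytosolic ribosomal protein list with a like suffix were bound in 3 of 5 cases (exact p = 0.247 against the others). Whether these genes encode copies of ribosomal subunits was not examined. RpL10Aa, which lacks that suffix, was counted among the others and was unbound.

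Non-coding genes away from coding TSSs were rarely bound. Beyond 500 bp from a coding TSS, 37 of 2742 genes of the ncRNA class, 1 of 258 tRNA genes, 1 of 29 snRNA genes and 2 of 240 snoRNA genes had a summit within 250 bp of their 5′ end. The strongest were Uhg4 and snoRNA:Psi28S-2949 with a shared peak (signal 4489), Uhg3 (3360) and lncRNA:roX2 (2920), and lncRNA:roX1 had a weaker peak (308). The roX RNAs act with msl-2 in dosage compensation. On chromosome 4, 36 of 80 genes (45.0%) were bound (log2 odds ratio against the large autosomal arms 0.77 ± 0.33, exact p = 0.0224). That difference did not pass without replicate 1 (exact p = 0.0532) and had the opposite sign among the strongest 2504 peaks (−0.51 ± 0.45).

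The DRE and Motif 7 had the opposite relation to signal from Motif 1. Promoter peaks with the DRE had a median signal of 296, against 589 without it, and those with Motif 7 had 252, against 537. Promoter peaks with Motif 6 had 1747, against 466.

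Motif 1 and DRE at summits were set against technical explanations. Base composition predicts similar ratios for shuffled motifs, but the log2 ratio exceeded the highest of 20 scrambles by 4.39 for the Motif 1 core and by 2.47 for the DRE. A property shared by any promoter predicts similar frequencies at bound and unbound promoters, but the log2 odds ratio of the Motif 1 core was 5.79 ± 0.22. These values argue against base composition for both motifs and against a property of any promoter for Motif 1, whose enrichment may come from direct binding or from recruitment through another protein. For the DRE a property of any promoter stays open in part, because its log2 odds ratio of 1.99 ± 0.08 was 0.85 ± 0.09 among promoters of the relaxed pooled list; no biological explanation was tested.

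Technical explanations stayed open in part for the binding of the 14 enriched gene lists, and no biological explanation was tested. Among promoters of the relaxed pooled list, 3 of 14 lists kept their call, so any ChIP signal at a promoter may account for part of the pattern. The Mediator list, with 29 genes in both tests, fell from a log2 odds ratio of 2.68 ± 0.63 to 0.83 ± 0.63. This background drops only unbound genes, and none of the Mediator list was dropped. Its odds ratio could therefore only fall, and the fall does not bear on the cause. Bound calls were shifted 1000 times along the genes of this background, and lists were called again against all protein-coding genes. The shifts gave a mean of 10.5 enriched lists, so most of the 14 calls could arise without a preference among promoters with ChIP signal. Against any ChIP signal as the whole cause, the genes of the 14 lists together had a log2 odds ratio of 1.32 ± 0.16 in this background. The lists enriched in each shift had 0.14 there on average and at most 0.64. If reads were drawn to the most transcribed genes, peaks at ribosomal protein promoters would be stronger, and their median log2 signal was higher by 1.25 ± 0.37 (permutation p = 0.00158). Promoter peaks of the other lists together differed from the remaining ones by −0.00078 ± 0.22, so this explanation may hold for ribosomal protein genes and is undecided for the others, whose transcription was not measured; control reads were not analysed.

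The share of peaks with the Motif 1 core was lower in the strongest 501 peaks (16.8%) than in the 501 peaks ranked under them (26.1%), a difference of −9.38 ± 2.58 points within 50 bp of the summit. A candidate explanation is that this window misses the motif where the summit lies farther from it. Within 100 bp the shares were 37.3% and 37.5%, a difference of −0.20 ± 3.06 points, as this explanation requires. Summits of the strongest group lay a median of −49 bp from the TSS, against −38 bp. No biological explanation was tested.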
